A study of Mus musculus with 2 samples.

How the data were processed

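H3K4me2 was measured by ChIP-seq in midbrain of mouse embryos at embryonic day 11.5, in 2 biological replicates of 1 group, per the labels. The labels give pools of 109 embryos for replicate 1 and 88 embryos for replicate 2, and a fragment size of 300 to 500 bp. The authors deposited 4 lists in narrowPeak format on mm10. Per the labels and the file descriptions that accompany them, 1 list was called on each replicate, 1 on both replicates pooled, each with control alignments, and 1, the replicated set, was derived from the other lists. The aligner, the peak caller and their versions are not given in the sources used here, nor is the rule behind the replicated set, and the control is not analysed here. Every peak of the replicated set was checked to be a peak of the pooled list.

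The value per peak in the seventh column is a ratio, read as the fold enrichment over the control that the authors' peak caller gave, from the narrowPeak format. The eighth column is the −log10 of the peak's p-value as the authors deposited it, and its lowest value in any list was 2.02. Both values were used only to describe, rank or filter peaks within a list. The files give no read counts, so the depth of the replicates is unknown, and neither the power to find weak peaks nor a counting error can be given.

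Peaks on the 21 chromosomes were kept, and 11 to 13 peaks per list on other sequences were left out. Genes came from GENCODE M21, with 21938 protein-coding genes, and sequence from GRCm38, the same assembly as mm10. No peak or gene ended beyond its chromosome in that sequence. Peaks were compared by the share of each peak covered by the other list, with 50% as the minimum, and by covered bases (Jaccard index). The same values were taken after 100 random placements of the peaks on the same chromosomes outside unsequenced stretches. A peak's class came from its centre: within 1 kb of a TSS of any annotated transcript, otherwise in an exon, in an intron or between genes. A gene was marked where a peak touched the 1 kb on either side of one of its TSSs. Its domain was the longest stretch of peaks, joined over gaps of at most 1 kb, that touched this window. CpG content was the ratio of observed to expected CpG dinucleotides within 500 bp of the gene's 5' end, in 10 bins of equal size. Random genes matched on it were drawn from all protein-coding genes of the same bin, the list's own members included.

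The 18 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Olfactory receptor genes, taken by symbol, were added as a level for silent genes, which made 19 lists. Some genes, such as Shh, Gli3 and Wnt1, belong to more than 1 list. For each list, the share of marked members was compared with all other protein-coding genes by a two-sided Fisher's exact test. The median domain width of marked members was compared with 10000 random lists of marked protein-coding genes by a two-sided permutation test, where at least 3 members were marked. Both were adjusted over the lists by the Benjamini-Hochberg method with a threshold of 0.05. The smallest p the random lists can give is 0.0002. Genes are not independent replicates, and the p-values speak of these gene lists in these libraries. Values of the replicate lists are given as mean ± SD of 2. With 1 group there was no comparison between groups.

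The text names, for each list, the 4 members with the widest domains and up to 4 members with no promoter peak in list order. It also names the 20 protein-coding genes with the widest domains (1 per domain), the 10 widest domains with no annotated TSS within 10 kb, and the 5 peaks with the highest fold enrichment. Alternatives fixed beforehand were each replicate list alone, the pooled list, peaks with a −log10 p of at least 5, the upper 50% of peaks by fold enrichment, the gene's 5' end as only TSS, TSS windows of 500 and 2500 bp, joining gaps of 0 and 3 kb, and random genes matched on CpG content. For peak overlap they were minimum overlaps of 1 bp and 90%, 50% of both peaks, the −log10 p threshold and equal list lengths. After the data were seen, replicated peaks at least 50% covered in both replicates, and each domain counted once per list, were added.

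Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, with figures by matplotlib 3.10.9. Overlap functions were checked against bedtools 2.31.1 on simulated intervals. The list tests were tested on simulated data with 21938 genes and lists of 20. Of 1000 lists with no effect, 2.6% passed an unadjusted 0.05 for marking and 4.7% for width. Of 200 lists per effect, the test of marking called 93.5% of those marked at 95% and 86.0% of those marked at 30%. The CpG-matched test of marking called fewer, 64% of those marked at 30%, and passed 3% of 1000 lists with no effect. Simulated genes were independent, and the simulated bins differed less in marked share than the real ones. For the matched test no list marked more often was simulated, so its power for such lists is not given. The test of width called 83.0% of 200 lists that were 2-fold wider.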

Results

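Dimethylation of lysine 4 on histone H3 (H3K4me2), a chromatin mark found at active and poised promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse midbrain at embryonic day 11.5. The samples formed a single group with 2 biological replicates of strain B6NCrl, each a pool of both sexes. Replicate 1 was made from the midbrains of 109 embryos and replicate 2 from those of 88 embryos. No other tissue, age or mark belonged to the design, so the comparisons were between the replicates and between groups of genes or regions within the same tissue. The peak lists give no read counts, and the depth of each replicate is unknown. Every coordinate is on mm10, and peak fold enrichments and p-values are the authors' own.

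The strongest peak in the replicated set covered the promoter of Egr1, an immediate early transcription factor gene, at chromosome 18, 34859111 to 34863289, with a fold enrichment of 60.3. It ranked 1 in each replicate list. The next highest peaks lay over the transcription start sites (TSSs) of Usp43 on chromosome 11 (58.9-fold, 67921100 to 67922938), Atp1b2, a sodium pump subunit, on chromosome 11 (54.8-fold, 69604070 to 69606634), Specc1 on chromosome 11 (54.6-fold, 61956419 to 61957805) and Pianp on chromosome 6 (53.0-fold, 124996340 to 124997727). Among these 5 peaks the lowest rank by fold enrichment was 6 in replicate 1 and 16 in replicate 2.

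Peaks near promoters were shared by the replicates more often than distal peaks. Of the replicate 1 peaks centred within 1 kb of a TSS, 93.6% were at least 50% covered by replicate 2 peaks, against 65.4% of the other replicate 1 peaks. For replicate 2 the shares were 87.2% and 44.7%. Promoter peaks were also stronger, with a median fold enrichment of 13.7 against 3.77 in replicate 1 and 23.8 against 4.53 in replicate 2. Peaks of equal strength were not compared, so location and strength are not separated here. Over all peaks, 33695 of 42053 replicate 1 peaks (80.1%) and 25537 of 38775 replicate 2 peaks (65.9%) were covered to that extent. Random placement of the same peaks on the same chromosomes gave 1.78% and 1.44%, and no more than 1.90% and 1.59% in 100 placements. By covered bases, 34.7 Mb were common to both lists, which is 92.7% of the 37.4 Mb of replicate 1 and 78.6% of the 44.1 Mb of replicate 2. The Jaccard index was 0.740, against 0.00855 after random placement. Peaks not shared were weak and narrow. Their median fold enrichment was 3.28 in replicate 1 and 3.75 in replicate 2, against 9.46 and 20.8 for shared peaks, and their median width was 205 and 288 bp, against 824 and 1292 bp. With a minimum coverage of 90% in place of 50%, the share fell to 26.1% for replicate 2.

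**Figure D1:**
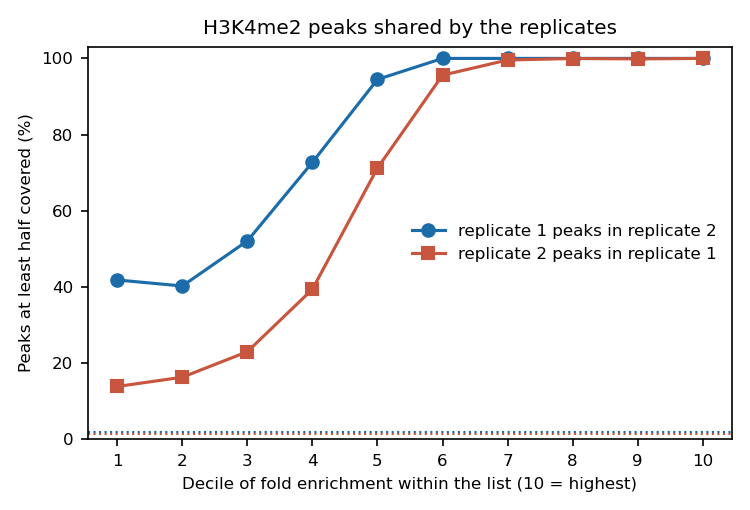
Share of the peaks of each replicate (y axis, percent) that are at least 50% covered by the other replicate's peaks, by decile of fold enrichment within the list (x axis, 10 highest), with dotted lines for the mean of 100 random placements. In the highest decile the share is 100% for both replicates, and in the lowest it is 41.8% for replicate 1 and 13.8% for replicate 2.

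The authors also deposited a list called on both replicates pooled, with 35386 peaks on the 21 chromosomes, and a replicated set of 31936 of these. Of the replicated peaks, 85.5% were at least 50% covered by replicate 1 peaks, 98.8% by replicate 2 peaks and 84.4% by both. The replicated set covered 41.2 Mb with a median peak width of 1014 bp. The 3450 pooled peaks outside it were narrower, with a median of 219 bp, and weaker, with a median fold enrichment of 2.94 against 12.7, and 18.7% of them were centred within 1 kb of a TSS. All 28458 pooled peaks that shared at least 50% of either peak's length with a peak in each replicate belonged to the replicated set. A further 3478 replicated peaks (10.9%) did not meet that rule, with a median fold enrichment of 3.39, and of these 3154 met it in replicate 2 and 301 in replicate 1.

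Promoters held the majority of the replicated peaks when TSSs of all annotated transcripts and a window of 1 kb were used. With only the gene's 5' end as TSS, or with a window of 500 bp, the share was under 50%. Of these peaks 57.6% were centred within 1 kb of a TSS, 4.45% elsewhere in an exon, 20.7% in an intron and 17.3% between genes. In random placements the promoter share averaged 6.39% (at most 6.71%), and introns and intergenic sequence took 40.2% and 50%. The promoter share of the replicate lists was 51.0% ± 1.68 (SD, n = 2), with 49.8% in replicate 2, so the replicated set lay above both replicates. Replicated peaks at promoters were also wider than the others, with a median of 1445 against 556 bp, and had a median fold enrichment of 20.6 against 4.87.

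A promoter peak, defined as a replicated peak touching the 1 kb on either side of an annotated TSS, was present at 14503 of 21938 protein-coding genes (66.1%). The replicate lists gave 66.4% ± 0.409 (SD, n = 2). They shared 14413 genes, with 99 genes marked in replicate 1 alone and 226 in replicate 2 alone. Marked promoters were rich in CpG dinucleotides. The median ratio of observed to expected CpG within 500 bp of the gene's 5' end was 0.708 for marked genes (interquartile range 0.544 to 0.828) and 0.169 for unmarked genes (0.106 to 0.260). From the lowest to the highest of 10 equal bins of this ratio, the share of marked genes went from 5.88% to 99.4%. CpG content therefore enters every comparison of gene lists below, and each list was also set against random genes matched on it. The matching was at the gene's 5' end, so the CpG content of other TSSs and the number of TSSs per gene were not matched.

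Domains were made by joining replicated peaks at most 1 kb apart. The widest H3K4me2 domain at a protein-coding gene covered Pou3f3 (ENSMUSG00000045515), a neural POU factor, at chromosome 1, 42683176 to 42714661, and was 31.5 kb wide, with 31.5 kb ± 0.531 (SD, n = 2) in the replicate lists. Sox2 (ENSMUSG00000074637), a neural progenitor factor, followed with 31.3 kb at chromosome 3, 34637907 to 34669157, and the nuclear receptor gene Nr2f2 (ENSMUSG00000030551) with 30.6 kb at chromosome 7, 70342068 to 70372653. Nr2f1, Pou3f2, Skida1, Zic4, Pax6, Ebf3 and Ptch1 had domains of 23.5, 23.0, 22.7, 22.6, 22.3, 21.8 and 21.8 kb. The domain named for Zic4 also held Zic1, and that of Skida1 also held A930004D18Rik and Mllt10. Meis2, Lhx2, Otx2, Bahcc1, Zfhx3, Pax5, Pax7, Pax3, Mn1 and Lhx5 completed the first 20, from 21.0 down to 16.7 kb. The widest single replicated peak was 20.8 kb, as wide as the Otx2 domain, so every wider domain is made of joined peaks. The order of the genes and these widths therefore depend on the joining. The median domain of a marked protein-coding gene was 2.16 kb and the 99th percentile 8.81 kb. Some of these domains differed between replicates by more than others, with 19.0 kb ± 3.94 at Ptch1 and 19.5 kb ± 7.88 at Zic4 (SD, n = 2).

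Genes that pattern the midbrain and the isthmus, the signalling centre at its border with the hindbrain, all carried a promoter peak (20 of 20). Their median domain width was 7.13 kb (6.54 kb ± 0.823 over the replicates, SD, n = 2), against 2.17 kb for random lists of marked genes (two-sided permutation test, adjusted p = 0.000567, from the smallest p that the random lists can give). With no joining of peaks the median was 4.38 kb, and by the permutation test the adjusted p was at most 0.00068 over the 11 alternatives. Otx2, a homeobox gene required for forebrain and midbrain, had 20.8 kb ± 0.172 (SD, n = 2), and the paired box genes Pax5, Pax7 and Pax3 had 19.1 ± 0.945, 18.0 ± 1.28 and 17.5 kb ± 0.282. The isthmus signals Fgf8 and Fgf17, named after their values were seen, had domains of 1.60 and 1.13 kb, below the median of all marked genes. In replicate 2 the Fgf8 domain was 2.41 kb, above that list's median of 2.22 kb. In the list of the ventral midbrain and the dopaminergic lineage, 12 of 14 genes were marked. The floor plate factors Foxa1 and Foxa2 and the secreted signal Shh led with 16.0, 11.1 and 10.8 kb, followed by Msx1 with 8.82 kb. Th, which encodes the rate-limiting enzyme of dopamine synthesis, and Aldh1a1 had no promoter peak in any of the 4 lists. The list's median of 2.69 kb did not pass the permutation test (adjusted p = 0.239). It passed with peaks joined over 3 kb (5.02 kb, permutation test, adjusted p = 0.000971; from 0.000971 to 0.922 over the 11 alternatives).

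Regulators of the telencephalon and hypothalamus, regions outside the dissected tissue, were marked at 20 of 21 promoters, all but Neurod6, and their median width was 2.36 kb (adjusted p = 0.610, two-sided permutation test). With peaks joined over 3 kb the median of 3.38 kb passed as wider (permutation test, adjusted p = 0.013; from 0.013 to 0.859 over the 11 alternatives), and with no joining it was 1.53 kb. Six3 had the widest domain at 12 kb, with 9.10 kb ± 4.12 over the replicates (SD, n = 2), and Emx2, Emx1 and Satb2 had 7.60, 5.10 and 4.64 kb. The Emx2 domain was 6.26 kb in replicate 1 and 13.1 kb in replicate 2. Promoter peaks were more frequent than among other protein-coding genes for the midbrain list (100% against 66.1%, two-sided Fisher's exact test, adjusted p = 0.00174) and for the telencephalon list (95.2%, adjusted p = 0.00831), but not for the ventral list (adjusted p = 0.191). Against CpG-matched genes, marked at 90.2% and 82.6%, neither of these differences passed (adjusted p = 0.194 and 0.139, permutation test). With all members marked, the midbrain list could get no lower p from this test. Over the 10 alternatives the adjusted p ranged from 0.000624 to 0.194 for the midbrain list and from 0.00395 to 0.925 for the telencephalon list, by exact or permutation tests. Among the upper 50% of peaks by fold enrichment the telencephalon share was 57.1%, on the other side of the background.

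Hox genes, which specify position in the hindbrain, spinal cord and trunk, were marked less often, at 17 of 39 promoters (43.6%, two-sided Fisher's exact test, adjusted p = 0.0101), and their domains were narrow, with a median of 0.812 kb (0.706 kb ± 0.122, SD, n = 2; two-sided permutation test, adjusted p = 0.000567). The widest were at Hoxa4, Hoxd8, Hoxd9 and Hoxd1, between 1.24 and 1.45 kb, and Hoxa2, Hoxa3, Hoxa6 and Hoxa9 were among the 22 without a peak. CpG-matched genes were marked at 89.7% (adjusted p = 0.00095, permutation test). Hox genes lie in 4 clusters and are not independent of each other, and the 17 marked genes shared 15 domains. Among the upper 50% of peaks by fold enrichment the Hox median was 1.23 kb. In replicate 2 alone 21 of 39 were marked and the difference from other genes, not matched on CpG, no longer passed (exact test, adjusted p = 0.108; from 1.98e-07 to 0.158 over the 10 alternatives).

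**Figure D2:**
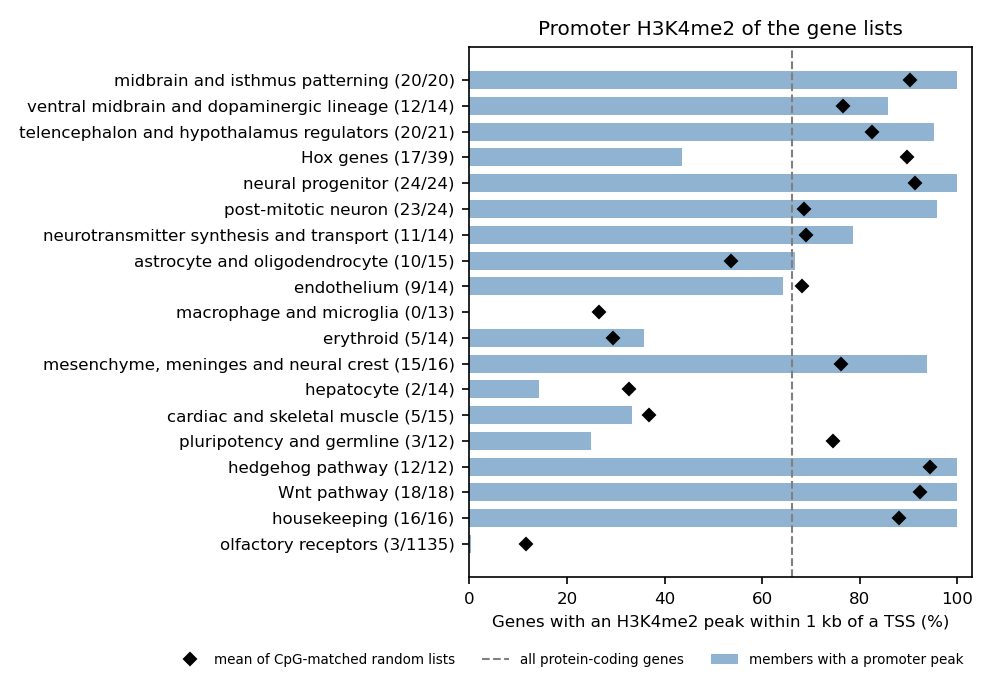
Share of the members of each gene list with an H3K4me2 peak of the replicated set within 1 kb of a TSS (bars, percent, with marked and total members in brackets), the mean of random lists matched on CpG content (diamonds) and the share among all protein-coding genes (dashed line, 66.1%). Hox genes reach 43.6% where CpG-matched genes reach 89.7%.

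Neural progenitor genes had the widest domains of the lists, with a median of 8.06 kb (8.48 kb ± 0.752, SD, n = 2; two-sided permutation test, adjusted p = 0.000567), and all 24 were marked. After Sox2, the widest were Zic1, Pax6, a regulator of neural and eye development, and Zic2, with 22.6, 22.3 and 14.6 kb. Genes of post-mitotic neurons were marked at 23 of 24 promoters with a median of 4.66 kb (4.77 kb ± 0.386, SD, n = 2; adjusted p = 0.000567, permutation test). Ebf3, Myt1l, Ebf2 and the RNA-binding protein gene Elavl4 had 21.8, 10.1, 9.93 and 8.50 kb. The Myt1l domain was 5.22 kb in replicate 1 and 10.1 kb in replicate 2. Nhlh2 had no replicated promoter peak but a domain of 5.23 kb in replicate 2. Members of the hedgehog pathway (12 of 12 marked, median 7.50 kb) and of the Wnt pathway (18 of 18, 4.64 kb) were wide as well (adjusted p = 0.000567 each, permutation test). With no joining of peaks the hedgehog median was 4.18 kb. Ptch1, the hedgehog receptor, Boc and Gas1 had 21.8, 9.03 and 8.07 kb, and Tcf7l2, Wnt5a, Axin2 and Fzd10 had 12.6, 12, 11.4 and 10.7 kb. Housekeeping genes, all 16 marked, had a median of 3.57 kb (adjusted p = 0.00194, permutation test), led by Polr2a, Gapdh, Tbp and Ywhaz with 4.18 to 5.92 kb. By the permutation test their difference no longer passed with only the gene's 5' end taken as TSS (2.74 kb, adjusted p = 0.175) or with no joining of peaks (2.37 kb, adjusted p = 0.111), and over the 11 alternatives its adjusted p ranged from 0.00085 to 0.175.

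Promoter peaks were more frequent than in other protein-coding genes for neural progenitor (adjusted p = 0.000467), post-mitotic neuron (0.0024), hedgehog (0.0171), Wnt (0.00239) and housekeeping genes (0.00537), by two-sided Fisher's exact tests. Against CpG-matched genes, the neuron list alone passed (95.8% against 68.7%, adjusted p = 0.00095, permutation test), and its adjusted p was at most 0.0152 over the 10 alternatives. The matching does not cover TSSs away from the gene's 5' end, where the widest domains of Map2 and Elavl4 in this list lay. The lists with every member marked can exceed their matched shares of 88.0% to 94.4% only slightly. Their p was already the lowest this test could give them, so they had no way to pass.

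Genes for neurotransmitter synthesis and transport were marked at 11 of 14 promoters. Slc17a6, the vesicular glutamate transporter gene, had a domain of 12.8 kb, and Gad1, which makes GABA, Slc32a1 and Gad2 had 8.26, 4.75 and 2.80 kb, while Slc17a8, Tph2 and Dbh had no replicated promoter peak. In the replicate lists the Slc32a1 domain was wider, at 7.99 kb ± 2.31 (SD, n = 2). Genes of astrocytes and oligodendrocytes were marked at 10 of 15, with Olig2, Slc1a2, Pdgfra and Mbp widest at 7.27, 6.06, 4.23 and 2.21 kb, and Gfap, S100b, Plp1 and Mog unmarked. The Pdgfra domain was 4.11 kb in replicate 1 and 7.28 kb in replicate 2. Neither list passed the test of frequency (adjusted p = 0.455 and 1, two-sided Fisher's exact test) or of width (adjusted p = 0.739 for both, permutation test).

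**Figure D3:**
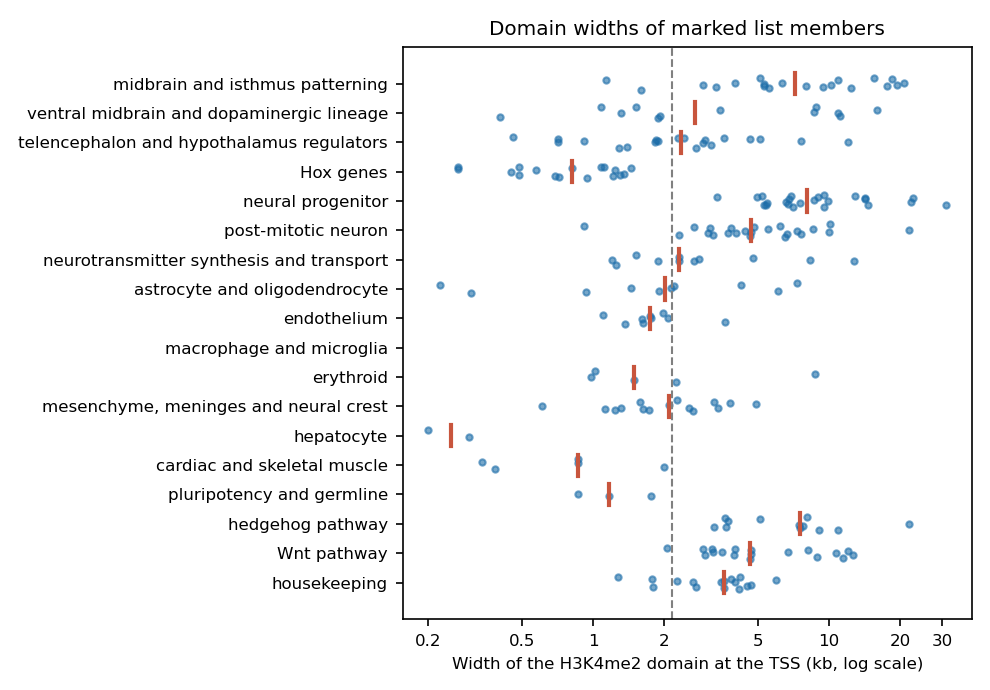
Width of the H3K4me2 domain at the TSS (x axis, kb, log scale) for each marked member of the fixed gene lists (points, spread vertically to be visible), with the list median (red bar) and the median of all marked protein-coding genes (dashed line, 2.16 kb). The medians of the neural progenitor, hedgehog and midbrain lists lie at 8.06, 7.50 and 7.13 kb.

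Markers of cell types other than neural cells were less often marked, with exceptions. None of 13 macrophage and microglia genes, Ptprc, Spi1, Csf1r and Cx3cr1 among them, had a promoter peak in any list (two-sided Fisher's exact test, adjusted p = 7.34e-06). Hepatocyte genes were marked at 2 of 14 promoters (exact test, adjusted p = 0.000467), the narrow peaks at Apob (0.299 kb, with none in replicate 1) and Trf (0.201 kb), and not at Alb, Afp, Apoa1 or Apoa2. Cardiac and skeletal muscle genes were marked at 5 of 15 (exact test, adjusted p = 0.0171), with Myod1, a muscle determination factor, widest at 2.00 kb ± 0.00778 (SD, n = 2), followed by Tnni3, Ckm and Myh7, and Nkx2-5, Myh6, Actc1 and Tnnt2 unmarked. The muscle median of 0.865 kb was narrow (adjusted p = 0.00831, permutation test), but against CpG-matched genes, with 1.63 kb, the difference did not pass (adjusted p = 0.177; from 0.000971 to 0.177 over the 10 alternatives). Erythroid genes were marked at 5 of 14 (exact test, adjusted p = 0.0286). These included Tal1, a factor also used in midbrain neurons, with 8.70 kb but 4.93 kb ± 5.26 over the replicates (SD, n = 2), and Epor, Klf1 and Gypa, while Gata1, Alas2, Slc4a1 and Hba-a1 were unmarked, although Slc4a1 had a promoter peak in each replicate list. Pluripotency and germline genes were marked at 3 of 12 (exact test, adjusted p = 0.00831), at Esrrb, Tfcp2l1 and Dazl, and not at Pou5f1, Nanog, Zfp42 or Dppa3.

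Against CpG-matched genes the pluripotency and germline list stayed lower (3 of 12 against 74.5%, adjusted p = 0.00095, permutation test), and its adjusted p ranged from 0.00095 to 0.0404 over the 10 alternatives. The macrophage (matched share 26.6%, adjusted p = 0.113), hepatocyte (32.8%, 0.362) and muscle lists (36.8%, 1) did not pass, nor did the erythroid list, whose 35.7% lay above the matched 29.5% (adjusted p = 0.886), by the same permutation test. With no member marked, the macrophage list could get no lower p from this test. The matched pools of these lists also held any olfactory receptors of the same bins, which can lower the matched shares. By the exact test the erythroid difference also failed in each replicate list (adjusted p = 0.119 and 0.107), and the muscle difference in replicate 2 (0.0679). Over the 10 alternatives the adjusted p ranged from 5.77e-06 to 0.113 for the macrophage, 2.1e-05 to 0.362 for the hepatocyte, 0.000117 to 1 for the muscle and 0.0284 to 0.886 for the erythroid list, by exact or permutation tests. Endothelial genes, with 9 of 14 marked, did not differ from other genes (adjusted p = 1, two-sided Fisher's exact test). Fli1, Sox17, Kdr and Cldn5 had domains of 1.76 to 3.61 kb, and Pecam1, Cdh5, Tek and Tie1 had none. Genes of mesenchyme, meninges and neural crest were marked at 15 of 16 (exact test, adjusted p = 0.0229), all but Col3a1, with Tfap2a, Prrx1, Foxc1 and Twist1 widest at 3.24 to 4.91 kb. The widest of these, at Tfap2a, was 2.50 kb in replicate 1 and 6.14 kb in replicate 2. In replicate 1 alone 14 of 16 were marked and the difference failed (exact test, adjusted p = 0.138), as it did with only the gene's 5' end taken as TSS (68.8%, 0.797, the highest over the 10 alternatives) and against CpG-matched genes (0.113).

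Olfactory receptor genes, a large family expressed in sensory neurons of the nose, served as a level for promoter calls at silent genes. Of 1135 such genes, 3 were marked (0.264%), and 3 in each replicate list, against 69.7% of other protein-coding genes and 11.5% of CpG-matched genes (adjusted p = 0.00095, permutation test). The matched pool included the receptors themselves, which lowers its share. The marked genes, named because they were so few, were Olfr1033 on chromosome 2, Olfr658 on chromosome 7 and Olfr94 on chromosome 17, with domains of 0.291, 0.418 and 1.20 kb. Reads shared between similar receptor genes were not tested as a cause of the low share.

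The widest domain with no annotated TSS within 10 kb lay between genes at chromosome 5, 28117209 to 28127350. It was 10.1 kb wide, and the nearest protein-coding TSS was that of En2, a homeobox gene of the midbrain and anterior hindbrain, 43.4 kb from its centre. Replicate 1 peaks covered 67.6% of it and replicate 2 peaks 87.9%. The next were inside Srgap3 (7.81 kb, chromosome 6, 112896362 to 112904174) and inside Pax3 (7.005 kb, chromosome 1, 78166971 to 78173975), of which replicate 1 peaks covered 31.9%. Intergenic domains followed whose nearest protein-coding TSSs were those of Cbx8 (5.92 kb), Zic3 (5.87 kb, 103.2 kb away), Nfe2l3 (5.76 kb, 261.3 kb away) and Sox11 (5.63 kb, 279.6 kb away). A domain inside Bcl11b (5.22 kb, chromosome 12, 107976228 to 107981446) and intergenic ones nearest to Zfp217 (5.12 kb) and Sox1 (4.87 kb, 35.0 kb away) completed the 10 widest.

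**Figure D4:**
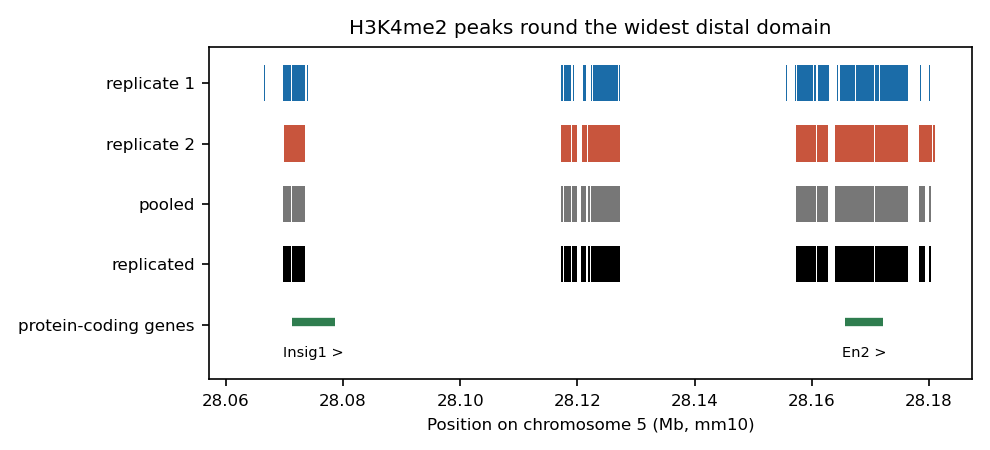
Peaks of the 4 lists (lines of blocks) and protein-coding genes with their strand (green) on chromosome 5 of mm10 (x axis, Mb), with the 10.1 kb domain that has no annotated TSS within 10 kb in the middle and En2 to its right. Peaks of all 4 lists cover the domain, in more pieces in replicate 1 than in replicate 2.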

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

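The replicated set held 11 peaks on 5 sequences outside the chromosomes. Their fold enrichment was at most 8.39, and each of these sequences also held peaks in both replicate lists. These peaks are a signal in data outside the comparisons, with no other group to set it against, and no explanation was tested.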

How the results depend on the processing

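The alternatives that require 50% coverage in both replicates, or count each domain once, were chosen after the data were seen, and all others before. The wider domains of the midbrain, neural progenitor, neuron, hedgehog and Wnt lists, and the narrower domains of Hox and olfactory receptor genes, stayed past the threshold under every alternative that gave a value, with adjusted p up to 0.00068 for the wider lists and 0.0263 for the narrower ones. For promoter frequency this held for the neuron list (adjusted p up to 0.0152), the pluripotency and germline list (up to 0.0404) and the olfactory receptors, and for none of the other 12 lists called. The cause of the changes below was not tested, except that CpG matching by construction raises or lowers the expected share. Widths could not be tested for lists with fewer than 3 marked members.

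Matching on CpG content left 1 list higher and 3 lower in place of 8 and 7. It ended the call at unaltered shares of 100% (midbrain, neural progenitor, hedgehog, Wnt, housekeeping), 95.2% (telencephalon), 93.8% (mesenchyme), 33.3% (muscle), 14.3% (hepatocyte) and 0% (macrophage), and put the erythroid share of 35.7% above its background. It also ended the narrower muscle width (0.865 kb). Lists at 100% or 0% were already at the limit, so the matched test could give them no lower p. Their lost calls are therefore no evidence that CpG content accounts for their shares. With the upper 50% of peaks by fold enrichment, 5 lists were higher and 1 narrower (3 before), the telencephalon share reversed to 57.1%, and mesenchyme (75%) and Wnt (83.3%) no longer passed. Shares that moved by over 1.5 times with no change of call were those of Hox (15.4%), muscle (6.67%), hepatocyte (0%), astrocyte and oligodendrocyte (40%), endothelial (35.7%) and olfactory receptor genes (0.0881%). With the gene's 5' end as only TSS, telencephalon (85.7%), erythroid (35.7%), mesenchyme (68.8%) and the housekeeping width (2.74 kb) no longer passed, nor did the housekeeping width with a gap of 0 bp (2.37 kb). A gap of 3 kb brought the ventral midbrain (5.02 kb) and telencephalon widths (3.38 kb) past the threshold. The pooled list ended the calls for Hox (53.8%) and erythroid genes (42.9%) and made the erythroid width (1.26 kb) pass, as did the −log10 p threshold and the coverage in both replicates (1.17 kb each). The latter ended the telencephalon call (85.7%). A window of 2500 bp ended those for Hox (51.3%) and muscle (40%), and 500 bp that for mesenchyme (87.5%). With 2500 bp the hepatocyte share was 28.6% and the macrophage share 7.69%, and with 500 bp the muscle share was 20%. The hepatocyte share was 7.14%, 1 gene, in replicate 1, with 500 bp, with the −log10 p threshold and with coverage in both replicates. The olfactory receptor share was 0.176% with 5' ends only.

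In single replicate lists, 4 to 6 lists were lower. Shares ranged from 43.6% to 53.8% for Hox, 33.3% to 40% for muscle and 87.5% to 93.8% for mesenchyme, and erythroid stayed at 42.9%. The pluripotency and germline width ranged from 0.930 kb in replicate 1, where it passed as narrower (permutation test, adjusted p = 0.0211; from 0.0211 to 0.240 over 9 alternatives), to 1.13 kb. The promoter share of peaks (57.6%) was 49.8% to 52.2% in the replicate lists, 53.8% in the pooled list, 62.5% with the −log10 p threshold, 84.4% in the upper 50% by fold enrichment, 46.6% with 5' ends only, 44.0% and 67.6% with windows of 500 and 2500 bp, and 64.3% with coverage in both replicates. Shared replicate 1 peaks were 69.4% at a minimum overlap of 90%, 55.4% at 50% of both peaks and 90.8% with the −log10 p threshold, and shared replicate 2 peaks 26.1% at 90%. Of 116 named genes, 51 changed width by more than the replicate SD in the upper 50% by fold enrichment, 49 with a gap of 0 bp and fewer than 49 under each other alternative. Unknown depth leaves open how many weak peaks each replicate missed.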

Other observations

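Apart from the CpG-matched tests of the Hox list and of the pluripotency and germline list, the tests in this part were chosen after the results they measure had been seen. Gene families were taken by symbol, 23 in all. The alpha protocadherins were symbols of Pcdha and a number, which leaves out any that begin Pcdhac. For the gamma protocadherins the corresponding Pcdhgc symbols were kept, so the sets are not built alike. Pcdha11 is the symbol of separate gene entries (ENSMUSG00000007440 and ENSMUSG00000102206), each counted. None of the 12 alpha and 22 beta protocadherins, adhesion proteins of neurons that lie in clusters, had a promoter peak in the replicated set, against 66.1% of other genes for the alpha genes (two-sided Fisher's exact test, adjusted p = 5.25e-06) and 66.2% for the beta genes (1.29e-10). CpG-matched genes were marked at 97.2% and 57.1%. Members of a cluster are not independent of each other, and the tests treat them as separate genes, so these p-values can be too small. Of 21 gamma protocadherins 12 were marked, with a narrow median domain of 0.463 kb, while 11 of 12 protocadherins outside the clusters were marked with 6.63 kb (adjusted p = 0.0004 for both widths, permutation test). The gamma share of 57.1% lay below the CpG-matched 88.1% (adjusted p = 0.00115, permutation test). Domains were wide in the Zic (14.6 kb, 5 of 5 marked), Pax (11.4 kb, 8 of 9), Irx (9.40 kb, 6 of 6), Lhx (7.0 kb, 8 of 8) and Sox families (4.91 kb, 18 of 19, adjusted p = 0.0004 for each, permutation test), and at histone genes (3.57 kb, 60 of 67, 0.0004). Zic1 and Zic4 shared a domain that counted for each, and counting each domain once was not done for families. Histone genes were marked less often than CpG-matched genes (89.6% against 97.2%, adjusted p = 0.00153, permutation test). All 78 mitochondrial ribosomal protein genes were marked, against 93.8% of CpG-matched genes. Few vomeronasal receptors (1 of 327), keratin-associated proteins (1 of 57) and defensins (0 of 64) were marked. Their promoters were poor in CpG, and CpG-matched genes were marked at 10.5%, 21.2% and 14.4%, well under the share of all genes. The matched pools included the members themselves, which lowers these shares. Each family lay below its matched share (adjusted p = 0.000767, permutation test). How far their promoter sequences are unique in the genome was not measured, so reads shared between members stay open as a cause.

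Of 8775 protein-coding genes in the upper 4 bins of CpG content, 105 (1.20%) had no promoter peak. They included 9 Hox genes and 14 clustered protocadherins. At 42 of the 105, fewer than 50% of the 32-base words within 500 bp of the 5' end occurred once in the genome. Of 200 random marked genes of the same bins, none had so few.

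For the unmarked Hox, pluripotency and germline, and alpha and beta protocadherin promoters, low CpG content is argued against as the whole cause, because CpG-matched genes were marked more often than each set (adjusted p = 0.00095 for Hox and for pluripotency and germline genes, p = 0.00020 for the protocadherins, 0.00020 being the smallest the permutations give). Reads shared with near-identical sequences stay open for the alpha protocadherins, of which 1 of 12 had over 90% unique words, although their median was 77.9%, none was under 71.3% and marked CpG-rich genes went down to 50.9%. Reads shared with identical sequences are argued against for the others. Their members with over 90% unique words were still marked less often than CpG-matched genes (15 of 36 Hox genes, p = 0.00020, 3 of 10 pluripotency and germline genes, p = 0.00040, and 0 of 18 beta protocadherins, p = 0.00020, permutation tests). Hox genes and these protocadherins lie in clusters, so the p-values given here for them treat dependent genes as separate and can be too small. Words were matched exactly, so a copy that differs by a base within each word counts as unique. For such copies the question stays open, as the aligner is not given. Of the unmarked alpha and beta protocadherins, 2.94% had a promoter peak in another list. The share was 11.1% for the pluripotency and germline genes and 27.3% for Hox genes. Peaks called elsewhere but left out of the replicated set are thus argued against for the protocadherins and the pluripotency and germline genes, but stay open for Hox genes. Signal below the threshold of every list cannot be seen in peak lists, so peaks too weak to be called stay open for all of these sets. That these promoters lack the mark in this tissue is a hypothesis for the beta protocadherins and the pluripotency and germline list, and no other tissue was there to test it.

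Replicate 1 had 3278 more peaks than replicate 2, but narrower ones. Different strong sites are argued against, since 100% of replicate 1 peaks in the upper 50% by fold enrichment were shared. Splitting of the same regions may account for it. Peaks of replicate 2 held 7465 pieces of replicate 1 beyond the first, against 1082 the other way round, an excess of 6383. Peaks that touched none of the other list numbered 7104 in replicate 1 and 10209 in replicate 2, so unmatched peaks do not give the surplus. The excess follows from these counts and the peak numbers, and is not a separate test. Why replicate 1 peaks are more broken is open, since depth is unknown, and a biological difference between the pools was not tested.

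Midbrain regulators had wider domains than telencephalon and hypothalamus regulators, with medians of 7.13 and 2.36 kb (two-sided permutation test, p = 0.00135), and more distal peaks within 50 kb of the 5' end, with 6.80 ± 4.10 and 3.0 ± 2.39 per gene (SD over 20 and 21 genes; p = 0.00053). Distal peaks were those centred over 1 kb from any TSS, including any joined into the gene's own promoter domain. The differences in width and in distal peaks are therefore not separate evidence. Both differences had the same direction in each replicate list, with p of at most 0.00262 (permutation test). The midbrain list had the higher CpG ratio (0.740 against 0.654, permutation p = 0.0371), but among marked genes of the same CpG bin its median width percentile was still 97.8 against 65.8 (p = 0.00191), which argues against CpG content as the whole cause. A candidate explanation is the regional identity of the dissected tissue. The lists also differ in other ways, such as when their genes are first used, and no forebrain sample was there to test it.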
